A study of Homo sapiens with 4 samples.

How the data were processed

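The series holds 4 arrays of RNA from cells that the labels call HL-60, 2 with a scrambled control and 2 with a miR-182-5p mimic, grouped by the sample titles. Per the labels' protocols, cells were grown in 20% serum, differentiated with DMSO, and transfected with 6 µl of 20 µM mimic and 12 µl of HiPerFect reagent. RNA was extracted with the mirVana kit and had an integrity number of at least 7, per the labels' protocols. Labelled cDNA was made with the Affymetrix WT PLUS kit, per the labels' protocols. The deposited values are gene-level log2 signals that the authors made with Expression Console, per the labels. The submitters' processing notes name RMA and Partek, without versions. The genome build is not given in the sources used here, so no coordinates are printed.

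A main table of 74341 probesets and a second table of 70523 hold the deposited log2 values, and all 70523 shared probesets had identical values on every array. No further scaling was applied. A platform annotation table listed 25324 probesets with a gene, of which 23781 named 1 gene and 1543 several; 49017 probesets of the main table are unnamed here. Symbols were brought up to date with a RefSeq table of assembly GRCh38.p14, used only for names and gene classes: 21497 probesets were matched by gene identifier and 2280 by symbol or synonym, and 4 kept the annotation's name. For the 528 genes with more than 1 probeset, the probeset with the highest mean over all arrays stood for the gene, which gave 22411 genes. Genes with a mean below the median of all probesets (log2 5.53) were left out as dim, 7098 in all, leaving 15313, of which 12717 are protein-coding.

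Mimic and control were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual and 20.7 prior degrees of freedom. On simulated arrays of 15313 genes it called 53 of 67 genes changed by 0.25, all 67 changed by 0.5 and all 66 changed by 1 on the log2 scale, with 7 false calls among the unchanged genes. The variances were drawn from the fitted prior and the genes independently, so these counts cannot show how the fit fares where related genes shift together. The 29 gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01. An estimated correlation and fry were the alternatives. On simulated arrays a list shifted by 0.1 gave a camera adjusted p of 3.04e-08, and 0 of 50 unshifted lists were called. The simulated genes were drawn independently, whereas the estimated correlation of the mitosis list was 0.30. The simulation therefore cannot show how often correlated lists are called falsely. List medians were also set against 10000 random lists matched in 10 bins of level. Probesets naming several genes (1185 tested) and those unnamed here (16738 tested) were fitted apart, and limma called 0 in each (smallest adjusted p 0.0655 and 0.167), with 96 and 1869 at an unadjusted p under 0.05 beside 59 and 837 that chance gives, and 7.23 and 4.89 prior degrees of freedom. Figures were drawn with matplotlib 3.10.9.

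Genes were named by a rule set before the data were examined: the 10 protein-coding genes of largest change in each direction among those past the threshold whose groups do not overlap, completed by smallest p where fewer passed; up to 4 members per list by smallest p, of which 2 are printed for the actin list; and 10 genes tied to miR-182-5p in any case, of which ADCY6 had no single-gene probeset. A planned test of miR-182-5p seed sites in 3' untranslated regions, and the part of the rule that depends on it, was not run, since no transcript sequence was used here; the list of reported targets stands in its place. The alternatives were quantile normalization, median centring, the second table, no or a stricter dim filter at the 75th percentile, the mean of probesets, an intensity trend, no moderation, the replicate number as a block, leaving out each array, an adjusted p of 0.10, and an unadjusted p of 0.05 with a 2-fold change. Robust moderation, a fit of protein-coding genes alone, and quantile normalization and no dim filter with the prior of the reported fit were added after seeing the data.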

Results

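Gene expression was measured on 4 Affymetrix whole-transcript arrays of cells that the labels describe as HL-60, a human promyelocytic leukaemia line, turned into neutrophil-like cells with 1.3% DMSO. A pair of arrays carried RNA of cells transfected with a scrambled control, and the other pair RNA of cells given a synthetic mimic of the microRNA miR-182-5p. All cells were harvested 24 hours after transfection. The median log2 signal of the tested genes was 6.98 and 7.01 on the control arrays and 6.99 and 6.98 on the mimic arrays. Over all probesets, before the dim filter, it was at most 5.53 on the mimic and at least 5.56 on the control arrays. The difference between the groups also varied with level. In 10 bins of level over all named genes, the median log2 change rose from -0.04 in the dimmest to 0.01 in the brightest. The arrays were thus not matched at every level. Across the 15313 genes tested, Pearson's r between arrays lay between 0.997 and 0.998, over genes, which are not independent replicates. The SD of the log2 differences was 0.0845 between the control arrays and 0.0815 between the mimic arrays, and control array 2 differed less from the mimic arrays (0.0795 and 0.0768) than from control array 1. The labels do not say that the samples of a group came from separate cultures, so p-values speak only for these samples, whose spread may be technical. With 2 arrays per group their number limits the precision. The p-values, standard errors and confidence intervals of limma rest mostly on a variance pooled over genes, with 20.7 prior beside 2 residual degrees of freedom. A gene with a wide spread between its own arrays is thus given a smaller error than that spread alone would give.

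The comparison of mimic with control arrays asks which transcripts of these cells differ after transfection with miR-182-5p. Most genes that passed the test were lower with the mimic, among them many pseudogenes and other non-coding genes. Among protein-coding genes, 6 members of the USP17L family of deubiquitinases fell, led by USP17L18, which went from 7.54 ± 0.30 (SD, n = 2) to 6.98 ± 0.015 (SD, n = 2) on the log2 scale. The olfactory receptor genes OR2T3 (log2 change -0.34, SE 0.066), OR52J3 (-0.33, SE 0.069) and OR51I1 (-0.33, SE 0.053) and the endogenous retroviral gene ERVH48-1 (-0.29, SE 0.055) fell as well. Without control replicate 1 the changes of USP17L18 and OR52J3 were -0.35 and -0.18, and without mimic replicate 1 that of OR2T3 was -0.20. NEUROG1, a transcription factor of neural development, rose by 0.30 (SE 0.059), from 6.46 ± 0.13 to 6.75 ± 0.024 (SD, n = 2 each). Protein-coding genes past the threshold numbered 1 higher and 11 lower in the fit of all genes. A fit of protein-coding genes alone, with infinite prior degrees of freedom, gave 7 higher and 18 lower.

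In all, 77 of the 15313 genes passed a Benjamini-Hochberg adjusted p of 0.05 in limma, 8 higher and 69 lower with the mimic, and the arrays of the 2 groups did not overlap in any of them. Over all tested genes 25.9% did not overlap, where chance gives 33.3%. At an unadjusted p under 0.05 there were 768 genes, 222 higher and 546 lower, beside 766 that chance gives. When each array was centred on its own median, the split became 64 higher and 74 lower, in a fit with infinite prior degrees of freedom. The count was 0 after added quantile normalization, without the filter on dim genes or without moderation. The median log2 change of the 69 lower genes stayed between -0.29 and -0.40 in all of the settings that tested every one of them. These genes were chosen for their changes on the same arrays, so that range is no separate support for the calls.

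The changes were small. With all 4 arrays, no gene reached a 2-fold difference, and 6 genes, none of them protein-coding, reached 1.5-fold. These limits depended on the control arrays: without control replicate 2 the log2 changes of RNA5SP311 and RNA5SP312 were -1.01 and -1.05, and that of USP17L18 -0.78, while without control replicate 1 they were -0.52, -0.47 and -0.35. The 95% confidence interval of the log2 change lay within 1.5-fold in either direction for 99.9% of the genes tested. The median standard error was 0.054. These intervals and errors rest mostly on the variance pooled over genes. For RNA5SP311 the standard error was 0.091, while the SD was 0.35 between its control arrays and 0.086 between its mimic arrays. Simulated arrays gave back 53 of 67 genes changed by 0.25 on the log2 scale and all 67 changed by 0.5. Their noise was independent between genes and drawn from the fitted prior. It held no shift shared by related genes, such as the median of 0.27 of the USP17L genes between the control arrays. These shares may therefore not carry over to the real arrays.

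**Figure D1:**
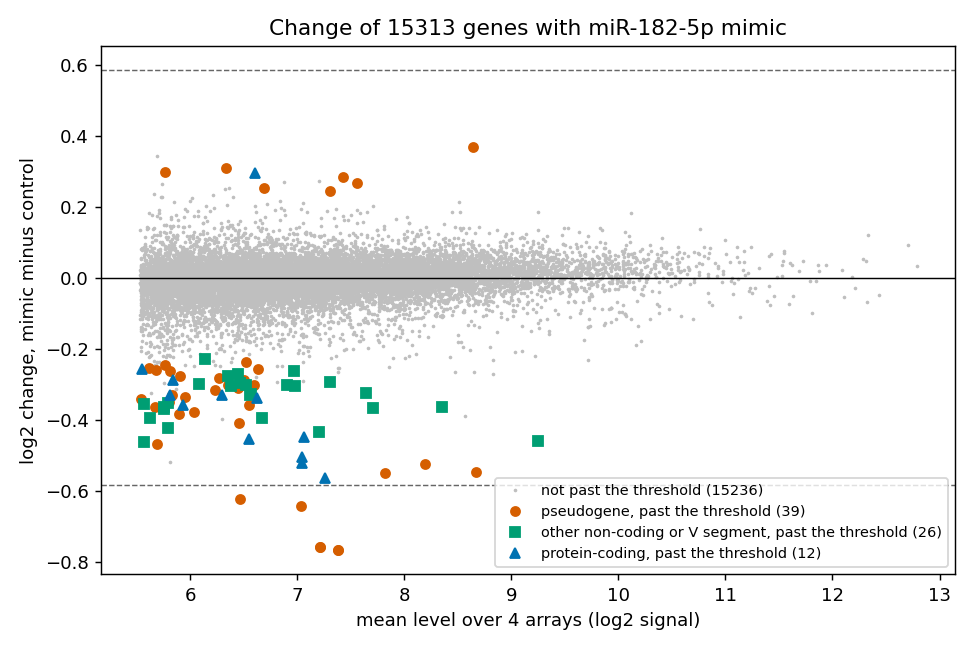
Log2 change (mimic minus control, 2 arrays per group) against the mean log2 level over the 4 arrays for 15313 genes. Coloured symbols are the 77 genes past the adjusted p threshold, 39 of them pseudogenes and 12 protein-coding, and the dashed lines mark 1.5-fold; 69 of the 77 lie below 0.

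Pseudogenes made up the largest class of the changed genes. Of the 77, 31 were pseudogenes and 7 transcribed pseudogenes, 10 long non-coding RNAs, 10 microRNA precursors, 12 protein-coding genes, 5 V segments, 1 V segment pseudogene and 1 snoRNA. Protein-coding genes were 15.6% of the changed genes and 83.0% of those tested. The largest change was that of the 5S ribosomal RNA pseudogene RNA5SP311, from 7.76 ± 0.35 to 6.99 ± 0.086 (SD, n = 2 each), 1.70-fold lower (limma with Benjamini-Hochberg, adjusted p = 6.18e-05), and RNA5SP317 carried identical values. The pseudogenes REXO1L2P (log2 change -0.55) and USP17L6P (-0.55), the imprinted long non-coding RNA KCNQ1OT1 (-0.46), and the precursors MIR4454 (-0.46) and MIR21 (-0.30) also fell. The largest rise was that of LOC283788, by 0.37, a transcribed pseudogene. These non-coding genes were chosen after their values were seen.

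The changed USP17L, REXO1L and 5S genes belong to repeated families. Their probes may bind transcripts of other members, so a value of a single member is uncertain. No sequences were used here, so how alike these members are was not checked. All 8 USP17L genes named on the array had a negative log2 change, with a median of -0.48, and the same genes were a median of 0.27 higher on control array 1 than on control array 2. Of 489 named 5S genes and pseudogenes, 388 had a negative value (median -0.08, and -0.04 without mimic replicate 1), and 17 of the 249 bright enough to be tested passed. Of 392 olfactory receptor genes and pseudogenes, 337 had a negative value (median -0.10), and 4 of the 44 tested passed. Random genes of matched level had medians of -0.02 for the 5S and -0.03 for the olfactory receptor genes. After quantile normalization the medians of the USP17L, 5S and olfactory receptor genes were -0.45, -0.04 and -0.05.

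The 6 lower USP17L genes named by rule had these log2 changes: USP17L12 -0.52, USP17L19 -0.50, USP17L15 -0.45, USP17L21 -0.45 and USP17L1 -0.36, beside USP17L18 at -0.56. Without control replicate 1 USP17L18 stood at -0.35, USP17L19 at -0.33 and USP17L21 at -0.30. Their limma adjusted p-values with Benjamini-Hochberg correction ran from 0.000588 for USP17L12 to 0.00424 for USP17L1, and that of NEUROG1 was 0.0133. KCNK18, a potassium channel gene, passed outside the rule with a log2 change of -0.26. To complete the higher genes to 10, the rule added 9 that did not pass, with limma adjusted p-values after Benjamini-Hochberg correction from 0.107 to 0.189. They were GALR3 at 0.21, THUMPD1 at 0.21, RAB27B, a GTPase of secretory granule release, at 0.20, MEX3B at 0.19, TAF1L at 0.22, ZNF98 at 0.19, CHRM4 at 0.25, DESI2 at 0.18 and PRKACG at 0.34. Single arrays moved 3 of them by over 1.5 times: PRKACG was 0.07 without control replicate 1 and 0.61 without control replicate 2, CHRM4 0.10 and 0.40, and TAF1L 0.12 without mimic replicate 2.

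**Figure D2:**
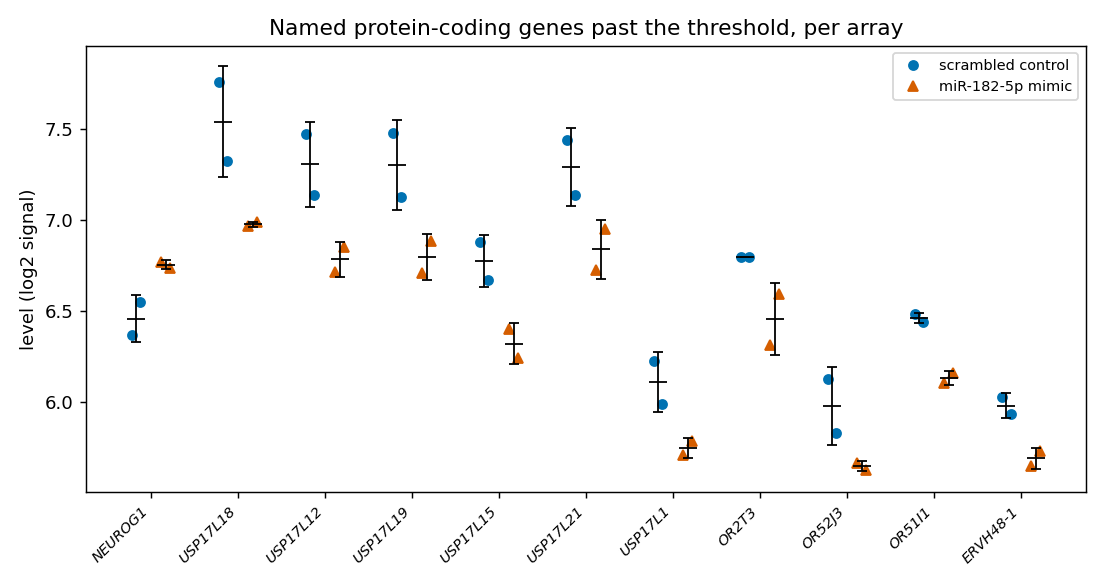
Log2 signal per array of the 11 protein-coding genes named by rule that passed the threshold. Circles are scrambled control and triangles miR-182-5p mimic arrays, and black bars give the mean and SD (n = 2); NEUROG1 lies higher and the other 10 lower with the mimic.

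Genes reported as targets of miR-182-5p in the literature had values near 0. Of 15 such genes tested, 0 passed the test, over all genes or adjusted over the list alone, 13 had a negative and 2 a positive log2 change, and the median was -0.02. The median of all tested genes was -0.0026. Quantile normalization and centring moved the list median to 0.0041 and 0.02 together with that of all genes, to 0.03 and 0.04. The list median was -0.05 without control replicate 1, -0.02 without control replicate 2, -0.07 without mimic replicate 1 and 0.01 without mimic replicate 2. FOXO3, a forkhead transcription factor, changed by -0.07 (95% confidence interval -0.18 to 0.05), MITF by -0.06, the lipid raft protein gene FLOT1 by -0.09, MTSS1 by -0.04, and the cortactin gene CTTN by -0.05. BRCA1 stood at 0.02 and the profilin gene PFN1 at 0.07. The confidence intervals of the 15 genes ran from -0.21 to 0.18. FOXO1 (-0.08), RECK (-0.05), CYLD (-0.0093) and the miR-182 precursor (0.12, 95% confidence interval -0.02 to 0.26) were too dim to enter the test and come from the fit without a filter. A transfected mature mimic is not the precursor that the last of these probesets targets. With limma's camera the list did not pass (adjusted p = 0.626).

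Genes of cell division gave the only list among 29 that passed limma's camera. The camera adjusted p was 0.0058 at a preset correlation of 0.01, and 0.981 (p = 0.306) with an estimated correlation. That estimate rests on 2 residual degrees of freedom, so the lost call says little about correlation. Of 29 mitosis genes tested, 22 had a positive and 7 a negative log2 change, and the median was 0.04. It lay at percentile 99.95 of level-matched random lists, whose genes need not be correlated like those of this list. Single members did not pass: the kinesin gene KIF11 stood at 0.14, the proliferation marker gene MKI67 at 0.12, the centromere kinesin gene CENPE at 0.12 and the topoisomerase gene TOP2A at 0.10. The list's call was also lost after quantile normalization (camera adjusted p = 0.0576, median 0.05, with a median of 0.03 over all genes), without control replicate 2 (0.738, median 0.03) and without mimic replicate 1 (0.488, median 0.02). It was kept without control replicate 1 (0.000333, median 0.05) and without mimic replicate 2 (0.0109, median 0.06). The 28 genes of S phase and replication were divided between 15 positive and 13 negative values (camera adjusted p = 0.737), with CCNE2 at 0.08, GINS1 at -0.08, TK1 at -0.07 and RFC4 at 0.06.

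No member of the migration lists passed. The 26 leukocyte adhesion and transendothelial migration genes had 12 positive and 14 negative values with a median of -0.0045 (limma camera adjusted p = 0.852). The selectin ligand gene SELPLG stood at -0.10, the small GTPase gene RAP1B at 0.09, ICAM1 at 0.06 and VAV1 at -0.05. Of 31 actin cytoskeleton and motility genes, 21 had positive values (camera adjusted p = 0.188), with the myosin light chain gene MYL9 at 0.11 and RDX at 0.10, which are not the largest values of the list. This list passed without the dim filter (0.0398) and without mimic replicate 2 (0.0109), and not with an estimated correlation on all arrays (adjusted p = 0.981, p = 0.595). All 7 chemoattractant receptor genes tested had positive values (camera adjusted p = 0.188), among them P2RY2 at 0.10, FPR1 at 0.08, C5AR2 at 0.08 and CMKLR1 at 0.03.

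Neutrophil granule and maturation genes did not pass either. Many were too dim to be tested: 12 of 23 mature neutrophil markers named on the array entered the test, and 9 of 17 specific and gelatinase granule genes. MNDA, CYBB and S100A8, with mean log2 levels of 3.90, 5.22 and 5.42 over the 4 arrays, were left out, while LYZ stood at 11.1. The values below therefore do not cover the whole of these lists. Azurophil granule genes numbered 12, with 6 positive and 6 negative values (limma camera adjusted p = 0.737), such as the lysozyme gene LYZ at 0.09, the elastase gene ELANE at 0.09, AZU1 at -0.05 and SERPINB1 at 0.05. Of 9 specific and gelatinase granule genes, 4 had positive values (0.886), with ORM1 at -0.14, PGLYRP1 at 0.10, CHI3L1 at -0.09 and CEACAM6 at -0.08. Mature neutrophil markers gave 7 positive values among 12 (0.626), with CEBPE at 0.12, S100A9 at 0.05, CEBPD at 0.04 and FCGR2A at 0.02. Promyelocyte and progenitor markers gave 5 among 10 (0.737), with CEBPA at 0.07, MEIS1 at 0.04, MPO at 0.04 and TFRC at -0.03. The 6 NADPH oxidase genes gave 3 (0.866), with HVCN1 at 0.03, RAC1 at 0.03, CYBA at -0.03 and RAC2 at 0.02.

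Lists of stress and signalling likewise held 0 genes that passed, over all genes or adjusted over the list alone. Of 14 interferon response genes, 8 had positive values (limma camera adjusted p = 0.737), with USP18 at -0.09, IFI35 at 0.08, EIF2AK2 at 0.07 and XAF1 at 0.06. Of 17 inflammatory and NF-kB target genes, 10 were positive (0.626), with CCL2 at 0.10, IER3 at -0.08, TNF at 0.08 and CXCL2 at 0.06. The DNA repair list had 11 positive values among 22 (0.737), with RAD50 at 0.09, RAD54L at -0.05, CHEK2 at -0.04 and EXO1 at 0.04. The p53 targets had 9 among 17 (0.737), with GADD45A at 0.10, DDB2 at -0.07, SESN1 at -0.05 and MDM2 at 0.05. FOXO targets had 6 among 15 (0.737), with TRIB1 at 0.06 beside GADD45A, FOXO3 and SESN1. Apoptosis regulators had 10 among 20 (0.926), with CYCS at 0.08, FADD at -0.06, BIK at -0.06 and BAK1 at -0.06. The unfolded protein and integrated stress list had 14 among 20 (0.626), with DNAJC3 at 0.11, ATF4 at -0.11, HYOU1 at 0.08 and HSPA5 at 0.04. Heat shock genes had 6 among 10 (0.366), with DNAJA1 at 0.09, HSPH1 at 0.09, HSP90AA1 at 0.07 and CHORDC1 at 0.05.

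Metabolic, growth factor and housekeeping lists gave these values. Cholesterol biosynthesis had 5 positive values among 15 genes (limma camera adjusted p = 0.737), with SC5D at -0.07, INSIG1 at -0.05, LSS at -0.05 and FDPS at -0.04. Hypoxia and glycolysis had 6 among 21 (0.626), with the glucose transporter gene SLC2A3 at -0.15, BNIP3 at -0.06, EGLN3 at -0.06 and P4HA1 at -0.03. TGF-beta signalling had 7 among 17 (0.926), with ID2 at -0.13, TGFBR1 at 0.13, ID3 at -0.10 and ID1 at -0.07. The small RNA pathway had 5 among 10 (0.886), with TNRC6A at -0.04, DROSHA at 0.03, XPO5 at 0.02 and PAN3 at -0.02. Replication-dependent histones had 2 among 9 (0.737), with H1-4 at -0.08, H2AC20 at -0.05, H2BC12 at 0.05 and H1-2 at -0.03. Cytosolic ribosomal proteins had 2 among 13 (0.737), with RPL27 at -0.05, RPS9 at -0.04, RPL18 at 0.04 and RPS14 at -0.03.

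Markers of other blood cells did not separate the groups. Monocyte and macrophage markers had 1 positive value among 13 (limma camera adjusted p = 0.63), with CX3CR1 at -0.07, TREM2 at -0.04, APOE at -0.03 and KLF4 at -0.03. Eosinophil and basophil markers had 3 among 6 (0.737), with PRG2 at -0.09, GATA1 at 0.07, EPX at -0.06 and HDC at -0.05. Lymphoid markers had 2 among 8 (0.608), with CD79B at -0.07, CD3D at -0.07, GNLY at -0.06 and CD79A at -0.06. Erythroid and megakaryocyte markers had 5 among 11 (0.886), with PF4 at 0.05, HBD at -0.04, KLF1 at -0.03 and TUBB1 at -0.02. The erythroid transcription factor genes GATA1 and KLF1 had mean log2 levels of 10.1 and 8.52 over the 4 arrays. Over all 29 lists, 421 genes were tested and 0 passed, over all genes or adjusted over the list alone, and their 95% confidence intervals ran from -0.26 to 0.27. No list passed camera with an estimated correlation (smallest adjusted p = 0.981) or fry (0.994). Both rest on 2 residual degrees of freedom, so few lists could pass them and their lack of calls says little.

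**Figure D3:**
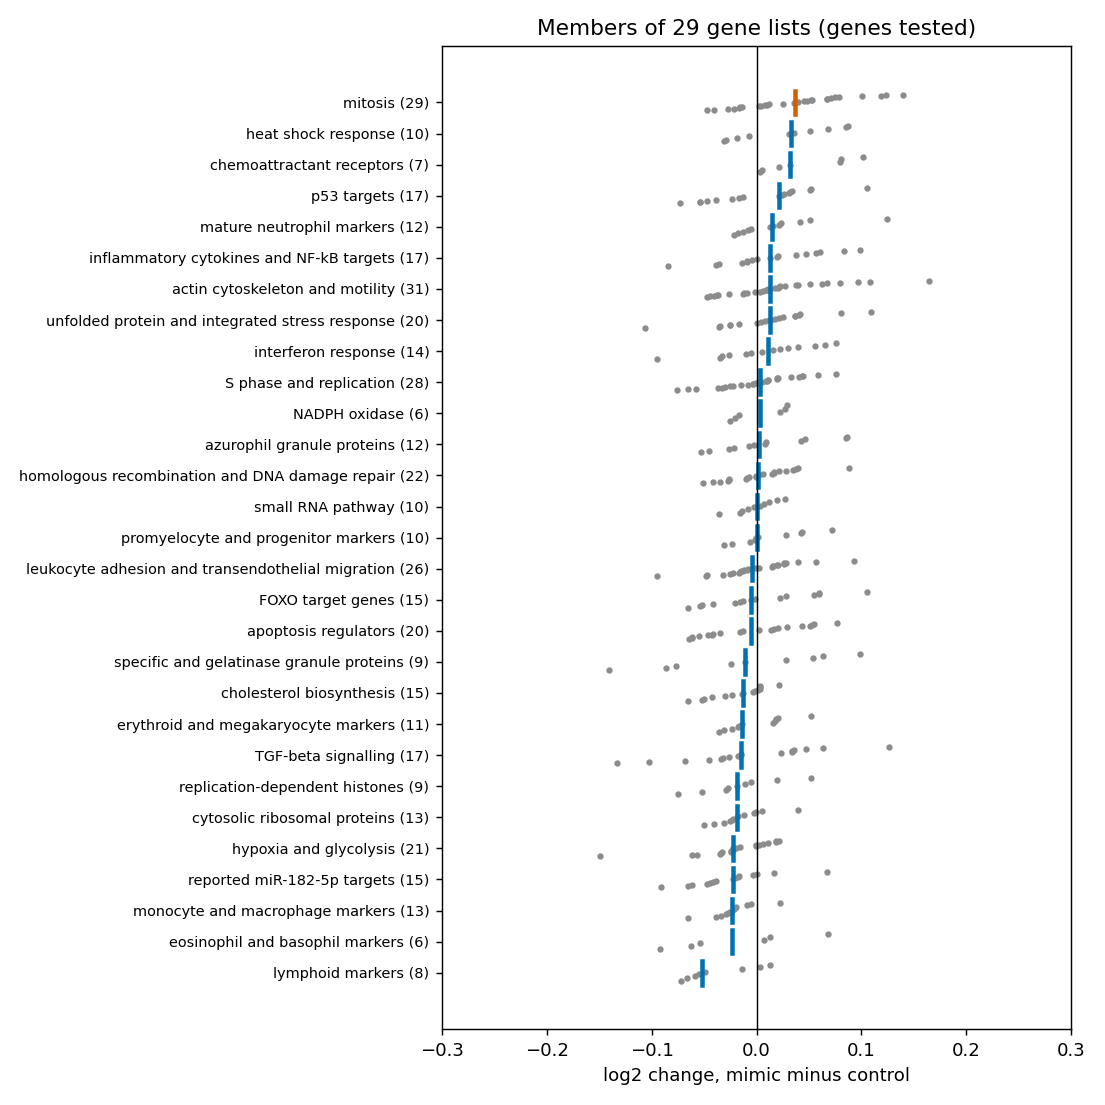
Log2 change (mimic minus control) of the tested members of the 29 gene lists, with the number of genes tested in parentheses. Grey points are genes and vertical bars list medians, in orange for the mitosis list, which passed limma's camera at a preset correlation, and in blue for the others; all medians lie between -0.05 and 0.04.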

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

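Robust moderation, the protein-coding fit and the fits with a held prior were chosen after the result was seen. The count of 77 genes (8 higher, 69 lower) fell to 0 (0 and 0) after quantile normalization, without the dim filter, without moderation, and at an unadjusted p of 0.05 with 2-fold; at an unadjusted p under 0.05 limma gave 927, 1272 and 519 genes in the first 3. The prior degrees of freedom, 20.7 in the reported fit, were 6.74 after quantile normalization and 6.80 without the filter. The 69 lower genes kept a median log2 change of -0.31 (interquartile range -0.40 to -0.26) after quantile normalization, beside -0.34 (-0.43 to -0.30). With the prior of the reported fit held, quantile normalization gave 63 genes (15 higher, 48 lower), 56 of them among the 77, and no dim filter gave 306 (28 and 278), all 77 among them. The re-estimated prior thus ended all calls without the filter, and 56 of the 77 after quantile normalization, where the others were lost with the prior held. Centring gave 138 genes (64 higher, 74 lower), robust moderation 183 (35 and 148), and protein-coding genes alone 25 (7 and 18). Prior degrees of freedom were infinite in these fits (as a median over genes for robust moderation), with the stricter filter and with 1 array left out. Most or all genes then shared a common variance, so these counts are not on the same footing as the 77. Leaving out 1 array gave 87 to 276 genes (10 to 75 higher, 63 to 201 lower), 276 without control 2 and 146 without mimic 2; the lone array of a group is assumed to vary like the others. The second table (78), the stricter filter (64, with 25 of the 77 tested and all 25 called), the mean of probesets (83), the intensity trend (84) and an adjusted p of 0.10 (96) stayed within 1.5 times of 77.

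The replicate numbers gave no sign of pairing (correlation of deviations -0.03 across genes). The labels do not say whether the samples were paired, and this value alone cannot settle it. With the replicate block 46 genes passed (2 higher, 44 lower), 45 of them among the 77.

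Of the 29 lists, 1 passed as reported, 2 without the dim filter, 0 after quantile normalization, 0 with an estimated correlation, 0 with fry, and 0 to 2 when an array was left out. Over 434 list results, 5 lost and 2 gained a call and 0 called ones reversed. Of the same list results, 44 differed in direction from the reported fit, with no call in either. Over 2262 results of named genes, 46 lost and 40 gained a call and 0 reversed. Leaving out 1 array moved the log2 change of 24 of the 77 genes by over 1.5 times and changed the sign of 0. The groups did not overlap in any of the 77, so no sign could change, and that 0 is no sign of stability. The cause was not tested where none is given. Lists were not run without moderation, with robust moderation or with a held prior, and 1 list had no gene left under the stricter filter. The seed site test and its alternatives were not run.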

Other observations

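All tests below were chosen after the result was seen, except the exchange of arrays, the splits, and the count of calls kept after quantile normalization.

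Beyond the lists, several classes of pseudogenes and non-coding RNAs had mostly negative log2 changes. Of 72 intronic transcripts named on the array 63 had a negative log2 change (median -0.08), of 71 U6 pseudogenes 65 (-0.10), of 68 U7 pseudogenes 60 (-0.12), and of 174 C/D box snoRNAs 142 (-0.10). These medians were -0.03, -0.07, -0.08 and -0.06 after quantile normalization. Without control replicate 1 the U6 and U7 medians were -0.04 and -0.06, and without control replicate 2 they were -0.17 and -0.19. Without mimic replicate 1 the intronic median was -0.05, and without mimic replicate 2 that of the C/D box snoRNAs was -0.06.

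Many of the lower genes, though not KCNK18 for example, belong to repeated or unspliced families, for which a shift of dim probes, a lower yield of small RNAs or less genomic DNA in the mimic samples could account. Quantile normalization left the 69 lower genes at a median of -0.31, beside -0.34 as reported. The shift that it removes was thus small next to their changes. These genes were chosen for large changes on the same arrays, so their median could hardly come near 0. The test therefore cannot show whether a shift of dim probes added to the calls. A criterion set before that result, that under 1 in 3 of the called genes would stay called if the shift were the cause, was met, with 0 of 77 kept. It was set aside afterwards because the prior degrees of freedom, shared by all genes, also fell from 20.7 to 6.74. With the prior held, 56 of the 77 stayed called. That prior was taken from the fit that gave the 77 calls, and it was held only after 0 had been kept. The 56 are therefore no separate support, and the calls of all 77 stay open. USP17L and REXO1L, not small RNAs, had a median of -0.513 (-0.34 without control replicate 1), which a lower yield of small RNAs alone would not give. These families were taken from the called genes, with 9 of their 10 genes called. Their low median was thus sure beforehand and is no separate test of that yield. Functional small RNAs and snoRNAs stood at -0.0769 (-0.05 after quantile normalization and without mimic replicate 2, -0.03 after centring), between the bounds set for and against. Silent intronless genes had a median of -0.0896 (-0.04 after quantile normalization), and other multi-copy families -0.04 (-0.01 after quantile normalization, 0.0045 after centring, -0.02 without mimic replicate 1, -0.07 without mimic replicate 2), the latter closer to 0 than less genomic DNA was set to give, while the former did not pass the bound set against it, so less genomic DNA stays open, as does an effect of the mimic. Of the 3 splits of the arrays into pairs, 1, the real one, called 77 genes and the others at most 0, with 768 genes at an unadjusted p under 0.05 in limma beside 721 and 1088, and prior degrees of freedom of 20.7 beside 5.00 and 4.64; 3 splits are too few for a share under 0.05.

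Reported targets lay near 0, for which a weak effect of the mimic or an exchanged pair of arrays might account. Under the other splits their median was at most 0.0387 from 0, under the 0.10 that an exchange was set to need. That bound assumes a lowering of at least this size by the mimic, which is not known. An exchange together with a weak effect therefore stays open. Their median of -0.02 lay at percentile 5.15 of level-matched lists, just outside the lowest 5%, and 4 of the other 28 lists lay lower (lymphoid 1.00, hypoxia 1.29, ribosomal 1.62 and histone genes 4.78), so the position does not single out the targets and a small lowering stays open. The level of the mature miRNA was not measured here.

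On all 4 arrays, erythroid genes were detected in cells labelled neutrophil-like, with log2 means of 10.4 for RHAG, 10.2 for HBZ, 10.1 for GATA1, 8.52 for KLF1 and 8.25 for ALAS2, while CA1 (4.75) and AHSP (4.71) were dim. Whether the RNA may hold cells of erythroid type was not decided. A count, with a list written after GATA1 and KLF1 had been seen, put 17 of 21 measured erythroid genes above the 75th percentile of probesets on every array, beside 9 of 26 granulocytic and 1 of 14 lymphoid ones. That count, like a ranking of levels tried before it, sets probes of different genes against a common level, and probes differ in brightness at equal abundance, so neither shows which cells were present. No profile of another line was used, and a mixture, another line and a trait of this HL-60 stock stay open.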
